A study of Arabidopsis thaliana with 12 samples.

How the data were processed

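RNA of whole Arabidopsis thaliana seedlings was hybridised to single-colour Affymetrix arrays of 22810 probe sets in 4 groups of 3 biological replicates, wild type and slim1-1 under arsenite or cadmium. Groups were taken from the labels, which give 20 µM arsenite or 100 µM cadmium and an age of 14 days. The labels' protocols describe 12 days without metal and 48 h on arsenite for every sample; the text names no cadmium, so the time of exposure of the cadmium samples was taken as unknown. The series design text states that the replicates are biological.

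The deposited values are on a log2 scale and were made by the authors with RMA (background correction, quantile normalization and probe set summary), named without a version in the submitters' processing notes; the annotation and options are not given in the sources used here. The deposited log2 values of the 6 arsenite arrays lie close together and those of the 6 cadmium arrays lie lower, with medians of 6.89 and 5.61 on average, so the sets do not share 1 normalization. Within a set the distributions are near each other but not identical. Differences between genotypes within a metal, and the interaction, are free of a step common to a set, whereas differences between metals are not. A step that depends on signal level does not cancel fully. The values carry no counts or detection calls, and the precision stated here comes from the spread between replicates. It does not cover signals near background or differences in RNA integrity.

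Control probe sets (64) were left out of all tests of genes. Of the other 22746 probe sets, the probe table used here lists 1 gene for 13513 and several genes for 503, and does not list 8730. Only the probe sets with 1 gene were tested, and of several probe sets of a gene the one with the highest mean over all arrays was kept (146 genes had more than 1), which left 13356 genes. Of these, 13286 were matched by gene number to the RefSeq table of assembly TAIR10.1, which gave locus tags and, for 1535 genes, a symbol other than the locus tag. Symbols of other genes come from gene lists written by hand before the data were examined. No coordinates are given, since the sources name no build.

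Each comparison was a contrast of 1 linear model with a mean for each of the 4 groups, fitted over the 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that all groups share the estimate of spread. Two-sided p-values were adjusted by the Benjamini-Hochberg method over the 13356 genes, with a threshold of 0.05. The 6 contrasts were slim1-1 minus wild type under arsenite and under cadmium, cadmium minus arsenite in each genotype, the interaction, and the genotype difference averaged over both metals. The overlap of the genotype calls was tested with Fisher's exact test, and values of control probe sets with an exact permutation test of 3 against 3 arrays. Differences between metals are printed relative to the median over all genes, whereas their p-values test the deposited differences, which hold the step.

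Gene lists for sulfur, metal, stress, hormone and tissue processes (26 lists, 399 members) were fixed before the data were examined, as were the contrasts, the threshold and all alternatives not named as added. Only 52 members had a probe set that the probe table lists with 1 gene, and only these are called measured. Other members may lie among the probe sets not listed, so results of a list hold for its measured members only. Measured were, for example, 3 of 18 members for sulfate assimilation, 4 of 20 for heat shock and 4 of 16 for anthocyanin synthesis. The 8 lists with at least 3 measured members were tested with camera (preset correlation 0.01), with an estimated correlation and fry as alternatives. The tested lists covered sulfate assimilation, glucosinolate synthesis, iron deficiency, heat shock, xenobiotic and mitochondrial stress, photosynthesis, ethylene response and anthocyanin synthesis. Statements that a list was higher or lower than other genes hold for the preset correlation unless the estimated one is named. The estimated correlation was above it, at 0.906 for the anthocyanin list and 0.593 for the xenobiotic list. It was 0.260 for sulfate assimilation, 0.218 for iron deficiency, 0.210 for heat shock and 0.085 for photosynthesis. Genes were named by a rule. For each contrast it took SLIM1, the 8 genes with the largest positive and the 8 with the largest negative difference among those past the threshold whose groups did not overlap (no such condition for the interaction and the average), and up to 4 members, by p, of each list with a called member or a camera call. It also took 15 sulfur genes whatever their p. SLIM1 and these 15 genes were not analysed by name, and named genes without a symbol in the tables could be left out.

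The scripts were tested on simulated data in which 200 of 13356 genes were changed. The noise was normal and independent, with 1 spread per gene, estimated from the real arrays, for all arrays. Unequal arrays and correlation between genes were not simulated, so recovery on the real arrays may be lower. For the genotype contrast, 98% of the genes changed by 1 on the log2 scale were recovered under arsenite and 99% under cadmium, and 84% and 70% of those changed by 0.5. For the interaction, 91% (change placed under arsenite) and 96% (under cadmium) of changes of 1 were recovered, and 36% and 26% of changes of 0.5. For the average, 92% and 97% of changes of 1 were recovered, and 31% and 24% of changes of 0.5. False calls were 3 of 185 calls under arsenite and 13 of 182 under cadmium. They were 5 of 132 and 5 of 127 for the interaction, and 8 of 131 and 5 of 126 for the average.

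Alternatives were quantile normalization over the 12 arrays, a shift of all arrays to a common median, the replicate number as a block, eBayes with trend and robust options, array weights, a filter on dim genes, the mean of a gene's probe sets, leaving out probe sets with shared sequence, other thresholds, fits of only the groups compared, and leaving out each array in turn. Tests of all 22746 probe sets and of gene families, splits of the arrays after each gene's average genotype difference was taken off, the overlap of calls made anew without each array, and the comparison of levels with the lower quartile of the arrays were added after the data were seen. Random regroupings used fixed seeds.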

Results

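Gene expression was measured on single-colour Affymetrix arrays in RNA from whole Arabidopsis thaliana seedlings aged 14 days. The seedlings were wild type (accession Col-0) or carried slim1-1, a mutant allele of SLIM1 (also named EIL3), a transcription factor of the EIN3-like family that governs the response of the plant to low sulfur. Seedlings of both genotypes were exposed either to 20 µM arsenite or to 100 µM cadmium. Both metals bind thiols, and both are detoxified with glutathione and phytochelatins, which are made from assimilated sulfur. Each of the 4 groups had 3 biological replicates, so 12 arrays were compared, and no untreated seedlings were analysed here. The number of arrays limits the precision: the median standard error of a difference between 2 groups was 0.0914 on the log2 scale. Replicates of a group correlated across genes with r of at least 0.992. SLIM1 itself, and 15 sulfur genes chosen by name before the data were examined (among them sulfate transporters, APS reductases, glutathione synthesis genes and SDI1), were not analysed here by name, because the probe table used covers only part of the array. The genotype labels were therefore not checked against the mutated gene.

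The deposited values fell into 2 sets. The medians of the 6 arsenite arrays lay between 6.85 and 6.94 and those of the 6 cadmium arrays between 5.58 and 5.64 on the log2 scale, a difference of -1.28 between the means of the medians. Within the cadmium set the medians of the 3 mutant arrays (5.62 to 5.64) lay above those of the 3 wild-type arrays (5.58 to 5.60). Within the arsenite set the mutant medians (6.89 to 6.94) also tended to lie above the wild-type ones (6.85 to 6.90), with overlapping ranges. Differences between genotypes under 1 metal stay within a set, whereas every difference between cadmium and arsenite also holds the step between the sets.

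**Figure D1:**
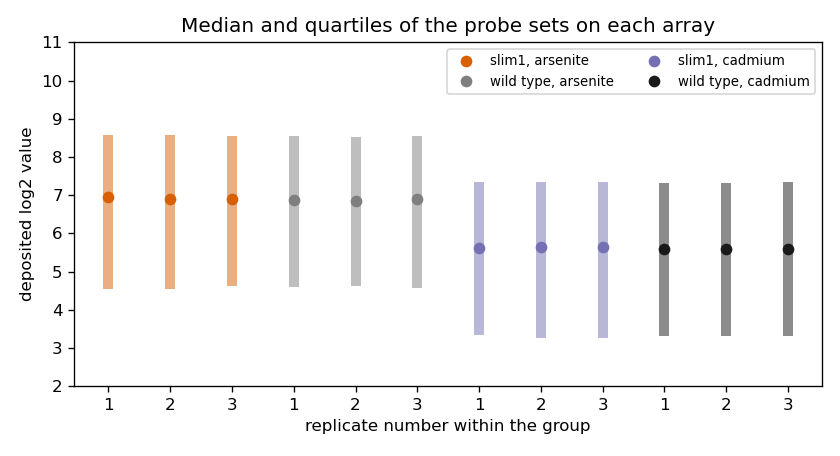
Median (point) and lower to upper quartile (bar) of the deposited log2 values of 22746 probe sets on each of the 12 arrays, by group and replicate number. The 6 cadmium arrays have medians of 5.58 to 5.64 and the 6 arsenite arrays of 6.85 to 6.94, and within a metal the arrays lie close together. The 3 mutant cadmium medians lie above the 3 wild-type ones. The mutant arsenite medians (6.89 to 6.94) also tend to lie above the wild-type ones (6.85 to 6.90), with overlapping ranges.

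The first comparison asked how slim1-1 differed from wild type under arsenite. AT1G12030 was 14.5-fold higher in the mutant (3.86 ± 0.34 on the log2 scale, SE, n = 3 arrays per genotype, adjusted p = 0.000352). Its wild-type level (4.34) lay below the lower quartile of those arrays (4.57 to 4.62) and is not shown to be above background, so the fold is not exact. SDI2 (AT1G04770), a sulfur starvation marker that represses glucosinolate synthesis, was 3.72-fold higher (1.89 ± 0.16, adjusted p = 0.000352), and AT4G20820, which encodes a berberine bridge enzyme-like oxidase, was 3.75-fold higher (1.91 ± 0.18, adjusted p = 0.000461). QQS, an Arabidopsis-specific gene that affects starch content, fell by 1.60 ± 0.25 on the log2 scale (adjusted p = 0.0111), and the CC-type glutaredoxin gene AT4G15660 fell by 1.08 ± 0.15 (adjusted p = 0.0041). The defensin-like gene PDF2.1 fell by 1.33 ± 0.28 (adjusted p = 0.0417), a call that was lost when mutant replicate 2 or 3 or wild-type replicate 2 or 3 was left out (adjusted p 0.107 to 0.179). Among the named genes, 8 others without a symbol in the tables are not described here.

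Of the 3 measured genes of sulfate assimilation, the ATP sulfurylase gene APS4 fell by 0.62 ± 0.11 (adjusted p = 0.0181), whereas APS3 (0.14 ± 0.15, adjusted p = 0.769) and the sulfite reductase gene SIR (-0.16 ± 0.09, adjusted p = 0.496) did not pass the test. The APS4 call was lost without mutant replicate 2 or wild-type replicate 2 or 3 (adjusted p 0.0582 to 0.0638). As a set the 3 genes did not pass camera's test (adjusted p = 0.0633, and 0.282 with an estimated correlation). Of 5 measured iron deficiency genes, 1 rose, IMA1 (AT1G47400), which encodes a small peptide that promotes iron uptake (1.32 ± 0.27, adjusted p = 0.0399). Of the 5, 3 passed when adjusted over the list alone. The IMA1 call was lost without mutant replicate 1 or 3 or wild-type replicate 1 or 2 (adjusted p 0.0533 to 0.172). The transcription factor gene BHLH101, which acts in iron uptake, was 2.3-fold higher without passing (SE 0.36 on the log2 scale, adjusted p = 0.148). As a set the iron deficiency genes were higher than other genes with the preset correlation (camera adjusted p = 0.0313). They did not pass with an estimated correlation (adjusted p = 0.282). The 7 measured xenobiotic and mitochondrial stress genes, among them UGT73B4 (-0.60 ± 0.17, adjusted p = 0.118) and GSTU25 (-0.58 ± 0.32, adjusted p = 0.479), had a median of -0.35 with 0 past the threshold in limma, 2 at an unadjusted p under 0.05 and 1 adjusted over the list alone. The set was lower than other genes with the preset correlation (camera adjusted p = 0.00562). It did not pass with an estimated correlation (adjusted p = 0.282). The 6 measured photosynthesis genes had a median of -0.09, with 0 past the threshold in limma and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.0313; adjusted p = 0.282 with an estimated correlation). The 4 heat shock genes (median 0.02, adjusted p = 0.907), the 4 anthocyanin genes (median 0.03, adjusted p = 0.907), the 4 glucosinolate synthesis genes (median -0.15, adjusted p = 0.0773) and the 3 ethylene response genes (median 0.05, adjusted p = 0.542) did not pass camera's test against other genes. In limma 0 of their members passed, with 0, 0, 1 and 1 at an unadjusted p under 0.05, and 1 glucosinolate gene passed when adjusted over the list alone. The means of the anthocyanin and ethylene lists (-0.01 and -0.20) had the opposite sign to their medians.

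In all, 140 of 13356 genes differed between the genotypes under arsenite, 61 higher and 79 lower in slim1-1 (limma, Benjamini-Hochberg adjusted p under 0.05), and 20 of them differed at least 2-fold. Shifting the arrays to a common median turned this split to 42 higher and 152 lower. The count was 744 with array weights. It was 250 without mutant replicate 1, 58 without mutant replicate 2, 50 without wild-type replicate 2, 88 without wild-type replicate 3, and 14 when the 6 arsenite arrays were fitted alone. In that fit of 6 arrays the calls of QQS, AT4G15660, PDF2.1, APS4 and IMA1 were lost (adjusted p 0.0847 to 0.206), and those of PDF2.1 and IMA1 also with a trend and robust estimate of spread (0.0903 and 0.0959). The 25S rRNA control probe set differed by -0.37 between mutant and wild type (exact permutation p = 0.4, two-sided; 0.1 is the smallest p that 3 against 3 arrays allow). The difference between 3' and 5' probe sets of control genes, a sign of RNA integrity, was lower in slim1-1 by -0.14 for GAPDH and higher by 0.12 for ubiquitin (exact permutation p = 0.1 each, all mutant arrays on 1 side of all wild-type arrays), and differed by -0.12 for actin (exact permutation p = 0.7).

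The second comparison asked the same question under cadmium. Some genes of small heat shock proteins, chaperones that bind unfolded proteins, were far higher in slim1-1. HSP17.6C (AT1G53540) was 19.2-fold higher (4.27 ± 0.21 on the log2 scale, SE, n = 3 arrays per genotype, adjusted p = 5.33e-07) and HSP17.6B (AT2G29500) 13.4-fold (3.74 ± 0.24, adjusted p = 5.25e-06). HSP15.7 (AT5G37670) rose less, by 0.70 ± 0.11 (adjusted p = 0.00219). HSP22 (AT4G10250) differed by 0.21 ± 0.10 without passing (adjusted p = 0.175), so 3 of 4 measured heat shock genes rose, and all 4 passed when adjusted over the list alone. The wild-type levels of HSP17.6C and HSP22 (3.25 and 3.28) lay below the lower quartile of those arrays (3.31 to 3.32) and are not shown to be above background, so the fold of HSP17.6C is not exact. AT1G52560, another small heat shock gene, rose by 2.21 ± 0.21 (adjusted p = 5.29e-05), and the J-domain protein gene AT1G71000 by 2.05 ± 0.27 (adjusted p = 0.000464). The heat shock list was higher than other genes (camera adjusted p = 3.57e-07; adjusted p = 0.0222 with an estimated correlation).

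All 4 measured genes of anthocyanin synthesis rose in slim1-1 under cadmium, also when adjusted over the list alone. These were DFR, the dihydroflavonol reductase (2.51 ± 0.25, adjusted p = 5.98e-05), UF3GT, which adds a sugar to anthocyanins (2.21 ± 0.22, adjusted p = 5.98e-05), UGT75C1 (AT4G14090), another anthocyanin glycosyltransferase (2.03 ± 0.22, adjusted p = 0.000125), and the malonyltransferase 5MAT (1.65 ± 0.22, adjusted p = 0.000441). The list was higher than other genes with the preset correlation (camera adjusted p = 9.63e-08). It did not pass with the estimated correlation of 0.906 (adjusted p = 0.0681). Of 7 xenobiotic and mitochondrial stress genes 4 rose, also when adjusted over the list alone (camera adjusted p = 0.00571; adjusted p = 0.415 with an estimated correlation): the glutathione transferase gene GSTU25 (1.39 ± 0.32, adjusted p = 0.0136), the glucosyltransferase genes UGT73B5 (0.62 ± 0.14, adjusted p = 0.0137) and UGT73B4 (0.55 ± 0.17, adjusted p = 0.0491), and 12CYS (AT5G09570; 0.56 ± 0.13, adjusted p = 0.0174). Leaving out wild-type replicate 3 ended the calls of these 4 genes (adjusted p 0.055 to 0.171). That of UGT73B4 also ended without any mutant replicate or wild-type replicate 2, after quantile normalization over the 12 arrays (0.0583), with a common median (0.0605) and with a trend and robust estimate of spread (0.0571), and that of 12CYS without mutant replicate 2 or 3.

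Sulfur genes moved both ways under cadmium. BGLU28 (AT2G44460), a myrosinase-like beta-glucosidase gene used as a marker of sulfur starvation, fell by 2.90 ± 0.25 (adjusted p = 2.88e-05), whereas SDI2 rose by 1.63 ± 0.16 (adjusted p = 5.29e-05). Of the 3 sulfate assimilation genes 2 fell, also when adjusted over the list alone: APS3 by 0.73 ± 0.15 (adjusted p = 0.00771) and SIR by 0.39 ± 0.09 (adjusted p = 0.0144), while APS4 differed by 0.19 ± 0.11 (adjusted p = 0.293). The list as a set did not pass camera's test (adjusted p = 0.188), whereas fry, which tests a list against no change, called it lower (fry adjusted p = 0.0457). Of 4 glucosinolate synthesis genes 1 rose, the glutathione transferase gene GSTU20 (0.41 ± 0.12, adjusted p = 0.0417), a call that was lost without any mutant replicate or wild-type replicate 1 or 2 (adjusted p 0.0677 to 0.164). Of the 4, 2 passed when adjusted over the list alone (camera adjusted p = 0.647). SAPX, a stromal ascorbate peroxidase gene, rose by 0.74 ± 0.08 (adjusted p = 0.00016), and its thylakoid counterpart TAPX differed by -0.13 ± 0.07 (adjusted p = 0.239). The dehydrin gene COR47 rose by 0.31 ± 0.09 (adjusted p = 0.0487), a call that was lost without mutant replicate 2 or 3 or any wild-type replicate (adjusted p 0.0513 to 0.176). The calls of GSTU20 and COR47 were also lost with a common median (0.0713 and 0.0719) and with the cadmium arrays fitted alone (0.0503 and 0.0937). AT1G12030 was 7.91-fold higher (2.98 ± 0.34, adjusted p = 0.00016), and AT2G20670 fell by 2.03 ± 0.15 (adjusted p = 1.34e-05). The 5 iron deficiency genes (median -0.21, camera adjusted p = 0.225), 6 photosynthesis genes (median 0.01, adjusted p = 0.827) and 3 ethylene response genes (median -0.11, adjusted p = 0.48) did not pass camera's test, with 0 members past the threshold in limma and 2, 0 and 0 of them at an unadjusted p under 0.05. The root hair expansin genes EXPA7 (0.41 ± 0.17, adjusted p = 0.139) and EXPA18 (0.50 ± 0.20, adjusted p = 0.138), the measured root markers, did not pass. Among the named genes, 7 others without a symbol in the tables are not described here.

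In all, 1646 of 13356 genes differed between the genotypes under cadmium, 884 higher and 762 lower in slim1-1, and 116 of them differed at least 2-fold. Shifting the arrays to a common median turned this split to 652 higher and 1057 lower. The count was 851 without mutant replicate 2, 958 without wild-type replicate 1 and 966 without wild-type replicate 3. The 25S rRNA control probe set was lower on every mutant array than on every wild-type array, by -0.68 on average (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 arrays allow). The 3' minus 5' difference of actin was higher on every mutant array, by 0.25 on average (exact permutation p = 0.1), while those of GAPDH (-0.07) and ubiquitin (0.00127) had exact permutation p = 0.3 and 1.

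**Figure D2:**
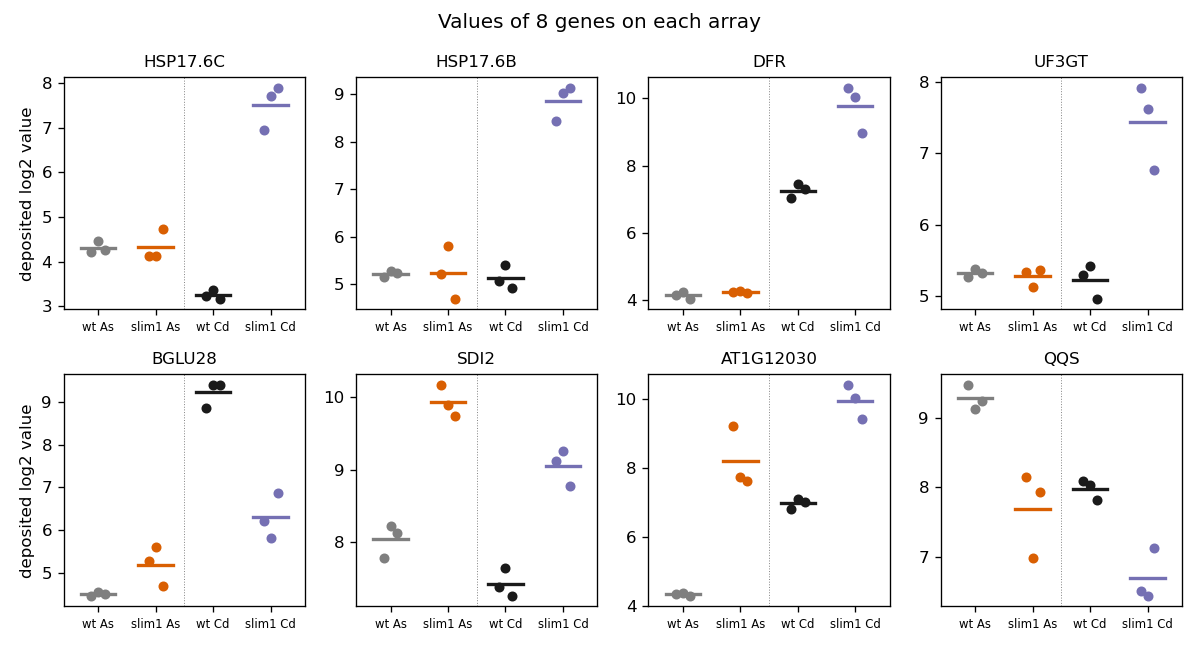
Deposited log2 values of 8 genes on each array (points) with the group mean (line), wild type and slim1-1 under arsenite (As, left of the dotted line) and cadmium (Cd, right); levels left and right of the dotted line come from separately normalized sets. HSP17.6C, HSP17.6B, DFR and UF3GT were higher in slim1-1 under cadmium by 4.27, 3.74, 2.51 and 2.21, BGLU28 was lower there by -2.90, and SDI2, AT1G12030 and QQS differed the same way under both metals.

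The third comparison asked which genes differed between the genotypes under both metals. The 2 contrasts share no arrays, but both use the same estimate of spread for each gene. A gene with a low estimate passes more easily in both. The lists are thus not fully independent, and the p-values of Fisher's test below are not exact. Of the 140 genes called under arsenite, 39 were also called under cadmium, 30 in the same direction and 9 in opposite directions. AT1G12030, AT4G20820 (1.91 under arsenite and 1.93 under cadmium) and SDI2 (1.89 and 1.63) were higher in slim1-1 under both, and QQS (-1.60 and -1.29) was lower. AT5G64190 was higher under arsenite by 1.30 ± 0.19 (adjusted p = 0.0065) and lower under cadmium by -1.24 (adjusted p = 0.00132), and its arsenite call was lost with the arsenite arrays fitted alone (adjusted p = 0.0581). The 12 genes higher under both metals exceeded the 4.04 expected of independent lists (Fisher's exact test, one-sided, p = 0.00056, adjusted p = 0.00112 over 4 tests), and so did the 18 lower under both against 4.51 expected (p = 3.44e-07, adjusted p = 1.37e-06). By the same exact test, the 7 genes higher under arsenite and lower under cadmium (3.48 expected, p = 0.0577, adjusted p = 0.077) and the 2 of the reverse kind (5.23 expected, p = 0.971, adjusted p = 0.971) did not. Across all 13356 genes, which are not independent replicates, the genotype differences under the 2 metals correlated with r = 0.125 and Spearman's rho = 0.129. The count of genes sharing a direction was 155 with array weights, 50 with a common median, and 59 among genes above the median level. It was 47 without mutant arsenite replicate 1, 19 without mutant arsenite replicate 2, 15 without wild-type arsenite replicate 2, 18 without mutant cadmium replicate 2, 15 without wild-type cadmium replicate 1 and 18 without wild-type cadmium replicate 2.

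**Figure D3:**
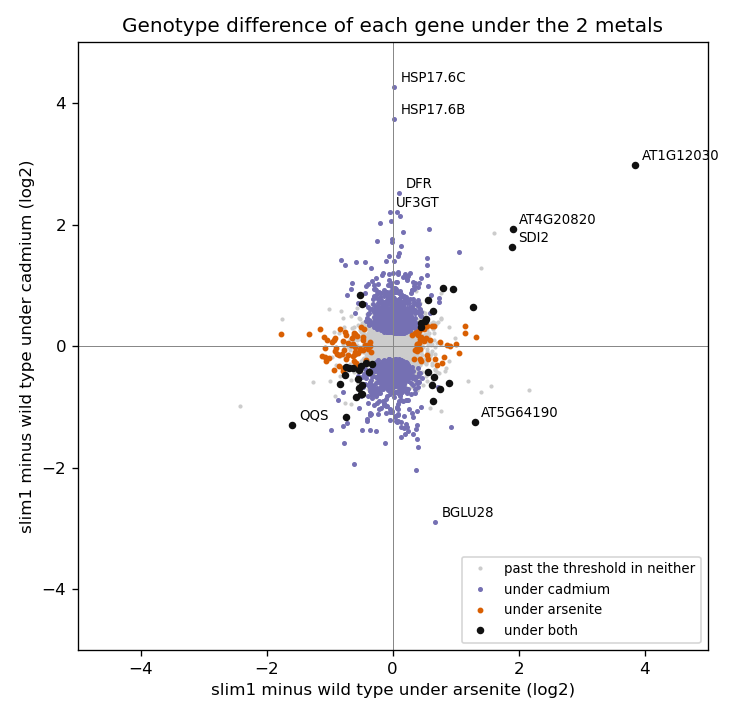
Difference between slim1-1 and wild type on the log2 scale for each of 13356 genes, under arsenite (horizontal axis) and under cadmium (vertical axis), coloured by whether the gene passed an adjusted p of 0.05 under arsenite, cadmium, both or neither. The 2 heat shock genes and the 2 anthocyanin genes named lie high near an arsenite difference of 0, while AT1G12030 lies at 3.86 and 2.98.

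The fourth comparison tested whether the genotype difference itself differed between cadmium and arsenite, which is the interaction of genotype and metal. A step common to all arrays of a set cancels in it. Metal cannot be told apart from dose or experiment here, since each metal had 1 dose and 1 set of arrays. A condition shared by the mutant samples of 1 metal does not cancel in the interaction and was not tested. The difference was larger under cadmium than under arsenite for HSP17.6C by 4.25 ± 0.30 on the log2 scale (SE, n = 3 arrays in each of 4 groups, adjusted p = 3.63e-05) and for HSP17.6B by 3.72 ± 0.34 (adjusted p = 0.000248). All 4 anthocyanin genes passed, DFR at 2.42 ± 0.35 (adjusted p = 0.00263), UF3GT at 2.25 ± 0.31 (adjusted p = 0.00189), UGT75C1 at 2.24 ± 0.31 (adjusted p = 0.00189) and 5MAT at 1.52 ± 0.30 (adjusted p = 0.0167). BGLU28 had the opposite sign, at -3.58 ± 0.36 (adjusted p = 0.000347), with a difference of 0.68 ± 0.25 under arsenite that did not pass (adjusted p = 0.268). The interaction of SDI2 did not pass (-0.27 ± 0.22, adjusted p = 0.59). Under arsenite the levels of HSP17.6C, DFR and AT1G52560 in both genotypes, UGT75C1 and 12CYS in slim1-1, and 5MAT and BGLU28 in wild type lay below the lower quartile of their arrays, so for these genes the arsenite side is not shown to be above background.

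The 2 ATP sulfurylase genes of the sulfate assimilation list went opposite ways, APS4 at 0.81 ± 0.15 (adjusted p = 0.0122) and APS3 at -0.88 ± 0.21 (adjusted p = 0.0363). Both passed when adjusted over the list alone, and the set did not pass (camera adjusted p = 0.731). SAPX (0.84 ± 0.12, adjusted p = 0.00199) and the calmodulin-like gene CML37 (2.24 ± 0.31, adjusted p = 0.00195) were among the positive interactions. Of 7 xenobiotic and mitochondrial stress genes 4 passed, also when adjusted over the list alone: GSTU25 at 1.97 ± 0.45 (adjusted p = 0.0289), UGT73B4 at 1.15 ± 0.24 (adjusted p = 0.018), UGT73B5 at 0.97 ± 0.20 (adjusted p = 0.018) and 12CYS at 0.79 ± 0.19 (adjusted p = 0.0355). The auxin response gene IAA29 had a negative interaction (-1.83 ± 0.47, adjusted p = 0.0481). Leaving out wild-type arsenite replicate 2 ended the calls of APS3, GSTU25, UGT73B4, UGT73B5, 12CYS and IAA29 (adjusted p 0.0505 to 0.111). Those of APS3, GSTU25, 12CYS and IAA29 also ended without most other single arrays, 8, 8, 9 and 11 of the 12 in all. Quantile normalization over the 12 arrays ended those of 12CYS and IAA29 (0.0535 and 0.0602), and a trend and robust estimate of spread those of GSTU25 and IAA29 (0.0809 and 0.12).

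By camera's test with the preset correlation, 4 lists differed from other genes, of which only the heat shock list passed with an estimated one. The adjusted p was 7.55e-08 for the anthocyanin list (0.0659 with an estimated correlation) and 2.15e-07 for the heat shock list (0.0202). It was 3.52e-05 for the xenobiotic list (0.138) and, downwards, 0.00547 for the iron deficiency list (0.138). In the iron deficiency list 0 of 5 genes passed in limma, 4 did at an unadjusted p under 0.05 and 2 adjusted over the list alone, with IMA1 at -1.17 ± 0.38 (adjusted p = 0.119) and BHLH101 at -1.78 ± 0.51 (adjusted p = 0.0738). The glucosinolate, photosynthesis and ethylene lists did not pass (adjusted p = 0.517, 0.118 and 0.288), and the ethylene list had a median of -0.17 and a mean of 0.07. In all, 574 genes had an interaction, 293 positive and 281 negative. Of these, 451 were also called under cadmium and not arsenite, 46 under arsenite and not cadmium, 9 under both with opposite signs and 68 under neither; the lists share arrays. The count was 1184 with array weights. It was 329 without mutant arsenite replicate 2, 281 and 334 without wild-type arsenite replicates 2 and 3, 311 without mutant cadmium replicate 2, and 280 and 348 without wild-type cadmium replicates 1 and 3.

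The fifth comparison averaged the genotype difference over both metals. AT1G12030 was higher in slim1-1 by 3.42 ± 0.24 on the log2 scale (SE, n = 6 arrays per genotype, limma adjusted p = 1.23e-05), AT4G20820 by 1.92 ± 0.13 (adjusted p = 1.19e-05) and SDI2 by 1.76 ± 0.11 (adjusted p = 1.19e-05), and QQS fell by 1.44 ± 0.18 (adjusted p = 0.000684). The sulfite reductase gene SIR fell by 0.27 ± 0.06 (adjusted p = 0.0202), although not without wild-type arsenite replicate 2 (adjusted p = 0.0504). The sulfate assimilation list was lower than other genes with the preset correlation (camera adjusted p = 0.0119). It did not pass with an estimated one (adjusted p = 0.128). Of its 3 members 1 passed the threshold, and all 3 when adjusted over the list alone. The list did not pass camera's test under either metal alone (adjusted p = 0.0633 under arsenite and 0.188 under cadmium). APS4 was called lower only under arsenite and APS3 only under cadmium, with interactions of 0.81 and -0.88. The average of this list thus merges different genes under the 2 metals. IMA1 averaged 0.74 ± 0.19 (adjusted p = 0.035), a call lost without any of 7 single arrays (adjusted p 0.058 to 0.0824) and with a trend and robust estimate of spread (0.0815). The averages of the heat shock list (3 of 4 higher, camera adjusted p = 6.34e-06; adjusted p = 0.0408 with an estimated correlation) and the anthocyanin list (4 of 4 higher, adjusted p = 3.15e-06; adjusted p = 0.113 with an estimated correlation) passed too, with members (HSP17.6C, HSP17.6B and the 4 anthocyanin genes) that also had an interaction with the metal. The other 5 lists did not pass (adjusted p 0.305 to 0.84), and 8 named genes without a symbol in the tables are not described here. In all, 1085 genes passed, 591 higher and 494 lower, a split that turned to 351 higher and 1017 lower when arrays were shifted to a common median. The count was 2068 with array weights. It was 705 without wild-type arsenite replicate 1, 707 without wild-type arsenite replicate 2, 644 without mutant cadmium replicate 2 and 676 without wild-type cadmium replicate 1.

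The sixth comparison set cadmium against arsenite in wild type. The median over all genes was -1.14 on the log2 scale, which holds the step between the 2 sets of arrays, and values are given relative to this shift. Metal and array set cannot be told apart. All limma adjusted p values of this comparison test the deposited differences. The shift itself therefore adds to the evidence for genes lower than the shift. Relative to the shift, BGLU28 was higher under cadmium by 5.83 (SE 0.25, n = 3 arrays per metal, adjusted p = 1.05e-09 for the deposited difference of 4.70). The iron deficiency genes IMA1 (5.39, SE 0.27, adjusted p = 4.44e-09) and BHLH101 (4.03, SE 0.36, adjusted p = 2.96e-06), the anthocyanin gene DFR (4.24, SE 0.25, adjusted p = 3.71e-08) and the auxin-conjugating enzyme gene GH3.3 (17.1-fold, SE 0.15 on the log2 scale, adjusted p = 7.81e-10) were higher too. The arsenite levels of BGLU28 and DFR lay below the lower quartile of those arrays. The calmodulin-like gene CML38 was lower by -6.00 (SE 0.25, adjusted p = 3.21e-11), the transcription factor gene WRKY53 by -2.79 (SE 0.27, adjusted p = 9.74e-09), the root hair expansin genes EXPA7 and EXPA18 by -1.74 and -1.21 (SE 0.17 and 0.20), and the sulfate assimilation genes APS4 and SIR by -1.45 and -0.83 (SE 0.11 and 0.09), while APS3, the third gene of that list, lay 0.37 (SE 0.15) above the shift. The labels used here give neither the exposure time of the cadmium samples nor the time of harvest of either set, so a difference in timing or handling is not excluded for them. Camera, which sets a list against other genes, found the anthocyanin list (adjusted p = 1.08e-12; adjusted p = 0.0182 with an estimated correlation) and the iron deficiency list (5.69e-08; adjusted p = 0.0182 with an estimated correlation) higher. Relative to the shift, all 4 anthocyanin genes and 4 of 5 iron deficiency genes lay above 0, the latter with IMA1 and BHLH101 far above and PYE (0.48), F6H1 (0.17) and S8H (-0.05) near it. As deposited, 2 of the 5 were higher and 3 lower. It also found the heat shock list (0.00636; adjusted p = 0.125 with an estimated correlation) and the xenobiotic list (0.000688; adjusted p = 0.232 with an estimated correlation) higher, with 4 of 4 and 4 of 7 members above the shift. All 4 of these calls were lost when the 12 arrays were quantile normalized together, which left adjusted p values of 0.0506 for the anthocyanin and iron deficiency lists, 0.209 for heat shock and 0.559 for the xenobiotic list. The sulfate assimilation, glucosinolate, photosynthesis and ethylene lists did not pass (adjusted p = 0.726, 0.786, 0.726 and 0.653), and for the last 3 camera's direction was opposite to that of the relative median. Of the named genes, 11 without a symbol in the tables are not described here. As deposited, 12956 genes passed, 202 higher and 12754 lower. Relative to the shift 6280 of these were higher and 6676 lower, a near-even split that follows from centring on the median over genes. Quantile normalization over the 12 arrays gave 7273 genes, 4162 higher and 3111 lower, and shifting the arrays to a common median gave 8986, 6482 higher and 2504 lower.

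The seventh comparison set cadmium against arsenite in slim1-1, with a median shift of -1.16 and the same confounding of metal and array set. All its limma adjusted p values again test the deposited differences, with the shift included. Relative to the shift, DFR was higher by 6.68 (SE 0.25, n = 3 arrays per metal, adjusted p = 2.35e-10 for the deposited difference of 5.52), HSP17.6B by 4.79 (SE 0.24, adjusted p = 5.37e-09), HSP17.6C by 4.35 (SE 0.21, adjusted p = 6e-09), IMA1 by 4.25 (SE 0.27, adjusted p = 8.88e-08) and BGLU28 by 2.28 (SE 0.25, adjusted p = 0.000813). The arsenite levels of DFR and HSP17.6C lay below the lower quartile of those arrays. ORA47, a transcription factor gene of the jasmonate pathway, was lower by -6.35 (SE 0.16, adjusted p = 6.08e-13), WRKY53 by -3.18 (SE 0.27, adjusted p = 3.89e-09) and EXPA7 by -1.32 (SE 0.17, adjusted p = 7.52e-09). The anthocyanin (adjusted p = 3.37e-30), heat shock (9.71e-18), xenobiotic (1.76e-11) and iron deficiency (1.6e-05) lists were higher than other genes by camera's test, and all 4 calls held with an estimated correlation (adjusted p = 0.00113, 0.00094, 0.0213 and 0.0213). Of their members, 4 of 4, 4 of 4, 7 of 7 and 3 of 5 lay above the shift. That of the iron deficiency list was lost under quantile normalization over the 12 arrays (adjusted p = 0.244). The sulfate assimilation, glucosinolate, photosynthesis and ethylene lists did not pass (adjusted p = 0.526, 0.526, 0.983 and 0.526). In this comparison 11 named genes without a symbol in the tables are not described here. As deposited, 12988 genes passed, 240 higher and 12748 lower. Relative to the shift 6311 were higher and 6677 lower, again by centring. Quantile normalization gave 7346, 4029 higher and 3317 lower, and a common median gave 8833, 6233 higher and 2600 lower.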

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

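The tests of a single deviating arsenite or cadmium array, of spread, of dose, of the joint normalization for the heat shock genes, of a chromosome segment, of the overlap called anew without each array and of splits with the average taken off were chosen after their results or closely related ones had been seen. The counts of other splits of the arrays and the test of single arrays for the genes shared by both metals were planned before.

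The genotype difference differed between the metals, by the interaction test, for 574 genes, although metal, dose and experiment cannot be told apart. Among the named genes the interaction on the log2 scale was 4.25 for HSP17.6C (AT1G53540), 3.72 for HSP17.6B (AT2G29500), 2.42 for DFR, 2.25 for UF3GT, 2.24 for CML37, 2.24 for UGT75C1 (AT4G14090), 2.14 for AT1G52560, 2.08 for AT5G16980, 1.97 for GSTU25, 1.52 for 5MAT, 1.15 for UGT73B4, 0.97 for UGT73B5, 0.84 for SAPX, 0.81 for APS4 and 0.79 for 12CYS (AT5G09570). It was -0.88 for APS3, -1.78 for AT2G37950, -1.83 for IAA29, -1.92 for AT3G60270, -2.07 for AT2G25200, -2.26 for AT1G72060, -2.40 for AT2G20670, -2.55 for AT5G64190 and -3.58 for BGLU28. Under arsenite HSP17.6C, DFR and AT1G52560 in both genotypes, UGT75C1 and 12CYS in slim1-1, and 5MAT and BGLU28 in wild type lay below the lower quartile of their arrays, so their interactions are not exact. The call of AT1G72060 ended without any of 9 single arrays (adjusted p 0.0531 to 0.0882) and with a trend and robust estimate of spread (0.0972). Those of GSTU25, UGT73B4, UGT73B5, 12CYS, APS3 and IAA29 ended without wild-type arsenite replicate 2 (0.0505 to 0.111), among others. Of 100 drawn splits of the arrays within the metals, 3 gave at least 574 genes, the real one included, with 1085 as the highest other, the split that exchanges the genotype labels of the cadmium arrays. Splits of the values as deposited also remove the genotype difference under cadmium, so they do not test the interaction alone. Those that mixed the cadmium arrays gave at most 1, and 6 that kept them apart by genotype and mixed the arsenite arrays gave 186 to 914. With each gene's average genotype difference taken off first, 1 of the 100 splits, the real one, gave 574 genes and the highest other 0. That average was computed with the real labels, so the other splits are not fully comparable with the real one. The split that exchanges the cadmium labels gives 0 by construction. These splits therefore do not decide whether chance is excluded for the interaction.

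Probe sets that the probe table does not list, and that the report's comparisons leave out, also differed between the genotypes. When all 22746 probe sets were tested, a choice made after seeing the data, 146 of 8730 such probe sets passed under arsenite (68 higher and 78 lower in slim1-1) and 1477 under cadmium (835 higher and 642 lower).

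Fewer genes differed between the genotypes under arsenite (140) than under cadmium (1646). A larger spread between the arsenite arrays as the whole cause is argued against by the variance of the genotype differences beyond noise, which stayed at or below 0.0252 under arsenite when any array was left out and at or above 0.0521 under cadmium. A single deviating arsenite array is argued against too, since leaving out 1 arsenite array gave at most 250 genes and leaving out 1 cadmium array at least 851. The genotype differences themselves were smaller under arsenite, with an SD beyond noise of 0.126 (0.095 to 0.159 without 1 array) against 0.237 (0.228 to 0.249) under cadmium. With array weights the counts were 744 and 2177. What stays open is whether metal, dose or experiment sets this, which cannot be told apart because each metal had 1 dose and 1 set of arrays. A condition shared by the mutant samples of a metal was not tested and stays open too. Control probe sets parted the genotypes under cadmium (25S rRNA -0.68, actin 3' minus 5' 0.25) and under arsenite (GAPDH -0.14, ubiquitin 0.12).

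Of the 10 splits of the 6 arrays of a metal, 1 (the real one) gave as many genes under arsenite (140, highest other 6) and 1 under cadmium (1646, highest other 0). Such splits are too few for a share under 0.05.

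Under cadmium, 7 of 8 small heat shock and chaperone genes passed and were higher in slim1-1, a count partly fixed by how the 8 were chosen. Of the 4 genes of the heat shock list, which were not chosen by their values, 3 passed. AT1G52560 and AT1G71000 are on no list and were named by the rule of the largest differences. The 8 were the 4 genes of that list with AT1G52560, AT1G71000, Fes1A (1.88 ± 0.15, adjusted p = 1.74e-05) and AT5G48570 (1.94 ± 0.35, adjusted p = 0.00386). Fes1A and AT5G48570 were picked, and the 8 put together, after their values were seen. The median difference of the 8 genes was 2.00, against 0.04 under arsenite, where 4 of the 8 (HSP17.6C, HSP22, AT1G52560 and AT1G71000) lay below the lower quartile of the arrays in both genotypes, so that the arsenite median does not show a lack of difference. A single deviating array is argued against by the 4 genes of the list fixed before the data were examined. Whichever cadmium array was left out, their median stayed at 2.15 or above and their camera adjusted p at 2.83e-06 or below (0.0438 with an estimated correlation). The median of the 8, which were chosen by their values, stayed at 1.803 or above. The separate normalization as the whole cause is argued against by a difference that lies within 1 set. Quantile normalization over the 12 arrays kept a median of 1.96, which adds little. It moved cadmium minus arsenite in wild type by a median of 1.21 but genotype differences under cadmium by only 0.0245. It could therefore hardly have changed this difference. A growth or harvest condition shared by the 3 mutant cadmium samples, whose 25S rRNA signal was lower (-0.68) and whose actin 3' minus 5' difference was higher (0.25), may also raise heat shock genes and was not tested, so it remains open beside an effect of the genotype.

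Under both metals, 30 genes differed between the genotypes in the same direction. A segment of a chromosome that differs between the lines, as the whole cause, is argued against by their positions: no run of 500 neighbouring tested genes held more than 4 of the 30, and random sets of 30 genes had a median of 4. The number of pairs within 20 genes of each other was 3 against 1.30 in random sets (permutation p = 0.137), while it was 37 against 28.9 for all genes called under arsenite (permutation p = 0.0689) and 4231 against 4033 for those called under cadmium (permutation p = 0.003), so a segment stays open for part of the cadmium calls. A single deviating array behind the whole overlap is argued against because the genes called anew without any 1 array and shared in direction came to at least 2.99 times the number expected of independent lists, although their number fell to 15 and 14 of the 30 were left without wild-type arsenite replicate 2, and that all 30 passed in the average without any 1 array decides nothing, since they were chosen by their calls. The expected number takes the lists of the 2 metals as independent, although they share the estimate of spread. Whether the difference comes from the slim1-1 mutation or from other differences between the lines stays open, since 1 mutant line was used.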

How the results depend on the processing

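Under the alternatives run, no named gene that passed the threshold, as reported or under the alternative, changed direction in a contrast of genotypes, in the interaction or in the average. Of the named genes reported as called, 5 of 17 under arsenite, 23 of 29 under cadmium, 17 of 24 with an interaction and 19 of 23 in the average kept an adjusted p under 0.05 under each alternative fit that gave them a value. The filter on dim genes gave none for genes it removed, and the stricter thresholds were applied to counts only. Signal over background is not known for these values, so dim genes could not be set apart except by the filter on the mean. The cause of each change below was not tested unless the setting itself gives it.

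Thresholds shrink counts by construction. At least 2-fold as a further condition left 20 genes under arsenite, 116 under cadmium, 137 with an interaction and 21 in the average, and an adjusted p under 0.01 left 34, 641, 143 and 336. Array weights, which set mutant arsenite replicate 2 at 3.08 against 0.636 and 0.436 for the others, raised the counts to 744 under arsenite, 1184 for the interaction and 2068 for the average. Fitting the 6 arsenite arrays alone gave 14 genes against 140, whereas fitting the 6 cadmium arrays alone gave 1462 against 1646. Both fits have fewer arrays behind the spread, so that alone does not account for the larger fall under arsenite. The arsenite count depended far more on the spread shared with the arrays of the other metal. The noise variance was 0.0165 under arsenite and 0.0126 under cadmium. The filter on dim genes, which tests fewer genes, gave 6390 (wild type) and 6410 (slim1-1) for cadmium against arsenite, and quantile normalization over the 12 arrays, which removes the step between the sets, gave 7273 and 7346. Testing all probe sets, an alternative chosen after seeing the data that tests more features, gave 296 under arsenite, 3227 under cadmium, 21997 and 21976 for the metals in wild type and slim1-1, 1179 for the interaction and 2169 for the average. Leaving out 1 array gave 50 to 250 genes under arsenite, 851 to 1322 under cadmium, 280 to 785 for the interaction, 644 to 1174 for the average, 12896 to 12915 for the metals in wild type and 12890 to 12953 in slim1-1. The 30 genes shared in direction became 50 with a common median, 155 with array weights, 59 with the filter on dim genes, 399 at an unadjusted p under 0.05 and 15 to 47 without 1 array.

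Of the lists tested, 3 passed camera under arsenite, against 0 with an estimated correlation and 1 with fry. Quantile normalization over the 12 arrays left 2 there, and the filter on dim genes 2. Under cadmium 3 passed, against 1 with an estimated correlation and 0 with the filter on dim genes. Fry also called 3 there, with the sulfate assimilation list in place of the xenobiotic list (fry adjusted p = 0.0457 and 0.0773). For the metals 4 passed in wild type, against 2 with an estimated correlation, 1 with the filter and 0 after quantile normalization, and 4 in slim1-1, against 2 with the filter. Fry called 7 in slim1-1, a count that is not comparable, since it tests a list against no change and so includes the step between the sets. For the interaction 4 passed, against 1 with an estimated correlation and 1 with the filter, and in the average 3, against 1 and 1. The filter left 6 of the 8 lists testable, without the heat shock and anthocyanin lists.

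The replicate numbers did not pair the samples: deviations of same-numbered mutant and wild-type arrays correlated with r of -0.33, 0.03 and -0.23 under arsenite and 0.00, 0.10 and -0.01 under cadmium. The replicate block gave 121 genes under arsenite, 1385 under cadmium, 438 for the interaction and 871 for the average, and 12962 and 12979 for the metals in wild type and slim1-1. Under arsenite it also let 4 gene lists pass camera's test, against 3 without it. With the block the calls of IMA1 and PDF2.1 under arsenite (adjusted p = 0.0594 and 0.0791), UGT73B4 and COR47 under cadmium (0.0714 and 0.0835), IMA1 in the average (0.0501) and the interactions of GSTU25, 12CYS, IAA29 and AT1G72060 (0.0545, 0.0632, 0.0856 and 0.0514) were lost, as were AT4G12500 and AT4G33720 in the average (0.0534 and 0.0509).

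A joint scaling removes the step between the sets, and differences between the metals that lay below 0 as deposited then changed sign for some genes. They are given whether or not they passed. Some passed, such as HSP17.6B in wild type after quantile normalization (limma adjusted p = 0.000403). Others did not, such as HSP17.6C there (0.447) and HAC1 and TAPX in slim1-1 (0.625 and 0.74). With a common median GSTU25 in wild type did not pass either (0.984). For such genes a change of sign is not shown. After quantile normalization over the 12 arrays the log2 difference in wild type was, in order, HSP17.6B 1.30, UF3GT 1.27, HSP15.7 1.21, SDI2 0.59, PYE 0.56, 5MAT 0.69, GR 0.44, APS3 0.43, RTE1 0.39. It was GSTU20 0.37, PSBW 0.082, HSP22 0.31, UPOX 0.34, TAPX 0.19, HAC1 0.17, UGT74C1 0.16, HSP17.6C 0.19, ZIP9 0.28, S8H 0.20. In slim1-1 it was GSTU20 0.92, NDB2 0.87, UPOX 0.79, HSP22 0.61, PSBW 0.25, PYE 0.46, ZIP9 0.54, GR 0.29. It was SDI2 0.29, UGT73B5 0.28, UGT74C1 0.22, HAC1 0.10, RTE1 0.13, TAPX 0.0297. With a common median it was in wild type HSP17.6B 1.26, UF3GT 1.25, HSP15.7 1.16, SDI2 0.73, PYE 0.69, 5MAT 0.69, GR 0.60, APS3 0.58, RTE1 0.54. There it was GSTU20 0.52, PSBW 0.48, HSP22 0.42, UPOX 0.40, TAPX 0.37, HAC1 0.36, PSAE1 0.36, UGT74C1 0.32, HSP17.6C 0.29, LHCB4.1 0.28, ZIP9 0.26, MTP2 0.24, S8H 0.16, EIN3 0.11, GSTU25 0.0079. In slim1-1 it was GSTU20 1.08, NDB2 1.02, UPOX 0.82, HSP22 0.71, PSBW 0.59, PYE 0.58, ZIP9 0.52, GR 0.48. There it was SDI2 0.47, PSAE1 0.40, UGT73B5 0.40, UGT74C1 0.37, LHCB4.1 0.36, HAC1 0.29, RTE1 0.27, TAPX 0.23, MTP2 0.18.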

Other observations

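The gene families and the plastid-encoded genes were chosen after the data were seen, and the splits of arrays were planned.

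Among the 9 genes called in opposite directions under the metals were 2 genes of transcription factors, picked after their values were seen. HAT2, a homeodomain gene of the auxin response, was higher in slim1-1 under arsenite by 0.65 ± 0.08 (SE, limma adjusted p = 0.00371) and lower under cadmium by -0.51 ± 0.08 (adjusted p = 0.00227). AT5G61590, an ethylene response factor gene, was higher by 0.75 ± 0.11 (adjusted p = 0.00729) and lower by -0.71 ± 0.11 (adjusted p = 0.00147). Another of the 9 was the berberine bridge enzyme-like gene AT1G26390 (0.90 and -0.61), which lost its arsenite call without mutant or wild-type replicate 2 and its cadmium call without any of the 6 cadmium arrays (adjusted p up to 0.0942 and 0.0924). Of genes with the same direction under both metals, SFP1, a sugar transporter-like gene, was higher (0.64 and 0.58, adjusted p = 0.0065 and 0.00174), and PSB27, a photosystem II assembly gene, was lower (-0.32 and -0.29, adjusted p = 0.0268 and 0.00947). The arsenite call of PSB27 was lost after quantile normalization over the 12 arrays (adjusted p = 0.0802) and without mutant replicate 1 or 2 or wild-type replicate 2 or 3 (up to 0.115).

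Of the 69 plastid-encoded genes, 56 had a negative difference between slim1-1 and wild type under arsenite, with a median of -0.12, and 55 under cadmium, with a median of -0.12. Of them 0 passed in either contrast in limma, with 5 and 3 at an unadjusted p under 0.05. After quantile normalization over the 12 arrays the medians were -0.10 and -0.10, and with a common median -0.18 and -0.17. The control probe set of 25S rRNA, an RNA without a poly(A) tail as most plastid RNA is, was also lower in slim1-1, by -0.37 and -0.68 (exact permutation p = 0.4 and 0.1, the smallest that 3 against 3 arrays allow being 0.1). Among 44 families, camera with the preset correlation called them under arsenite (adjusted p = 0.0037; adjusted p = 0.953 with an estimated correlation) and not under cadmium (adjusted p = 0.318). The PUB family of ubiquitin ligases was the other call under arsenite (9 genes, 8 with a negative difference, adjusted p = 0.0227; adjusted p = 0.535 with an estimated correlation). Camera called no family under cadmium or for the interaction, while fry, which tests a family against no change, called BGLU (20 genes, 11 with a positive difference, adjusted p = 0.0412) and IAA (7 genes, 5 with a negative difference, adjusted p = 0.0412) under cadmium. In the average camera called the plastid-encoded genes (adjusted p = 0.00299; adjusted p = 0.945 with an estimated correlation).

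Of the 10 splits of the 6 wild-type arrays, 1 (the real one) gave as many genes as cadmium against arsenite (12956, highest other 0), and likewise 1 of the 10 splits of the 6 mutant arrays (12988, highest other 0). Again 10 splits are too few for a share under 0.05. For the genotype difference averaged over metals, 1 of 100 drawn splits, the real one, gave 1085 genes, so chance is excluded at a share of 0.05 for the case of no genotype difference under either metal. The highest other gave 918 and kept the cadmium arrays apart by genotype while it mixed the arsenite arrays, and splits that mixed the cadmium arrays gave at most 1.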
